A study of Rattus norvegicus with 24 samples.

How the data were processed

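RNA was measured in 24 heart samples of 12 rats, 6 labelled CTL and 6 labelled DAAO, with a left ventricular sample that includes the septum and a right ventricular free wall sample per animal number. The 4-digit number in each label was read as the animal, since each number occurs once per ventricle and always in the same group. No label states this or says that numbers stand for separate rats, so p-values strictly measure the spread between these samples. The labels give no sex, dose, time or species of the enzyme. Per the labels' protocols, hearts were snap frozen, RNA was extracted with Trizol, and libraries were made and sequenced as paired ends by Novogene. Per the submitters' processing notes, STAR 2.7.0a, FastQC and DESeq2 1.26.0 were used with the genome build Rnor_6.0. The read counter and the annotation are not given in the sources used here, and neither is whether counting used strand, so genes that overlap or share sequence with near copies are uncertain.

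The authors deposited 2 tables of normalized counts, a signal of gene counts divided by 1 size factor per sample, computed separately for each ventricle, for 32883 Ensembl gene numbers. All values above 0 in all 24 libraries were whole multiples of the library's smallest value (100% within 1e-06), so reads per gene were recovered by division. Recovered reads ranged from 15363539 to 23263897 per library in the left and from 13280705 to 18777633 in the right ventricle. At this depth genes with a mean of 10 rest on few reads per library, and differences at that level are less precise. The tables were normalized separately, so levels were tested within a table, and across tables only as a difference of within-table differences. Every pair of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 12.3), so no library was counted as a repeat of another.

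Deposited values are not counts, so the main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend and Benjamini-Hochberg adjustment, two-sided, at an adjusted threshold of 0.05. Genes with a mean deposited value of at least 10 over the 12 libraries of a table were tested. Fold changes on this scale understate the change of genes with low values. The difference between the ventricles was the left minus the right DAAO effect in 1 fit over all 24 libraries, for genes tested in both tables. A fit with the animal as a block was the alternative. Deviations from the group mean of the left and right libraries of the same number correlated across genes with r from 0.06 to 0.79, median 0.55, and for 9 of 12 animals the own right ventricular library correlated best. The exceptions were the CTL animals C_7118, C_7120 and C_7123, at r of 0.060, 0.057 and 0.254, while the 6 DAAO animals had r of at least 0.511. The left library of C_7118 correlated at 0.499 with the right library of another CTL animal. Whether CTL libraries are wrongly paired was not tested. Because the numbers are taken as the same animals, the blocked count is printed beside the unblocked one. Library measures were compared with exact permutation tests over the 924 assignments of 12 libraries to 6 and 6, two-sided, with Benjamini-Hochberg adjustment over 6 tests.

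The reference pairs gene symbols of another rat assembly, GRCr8, with other identifiers, and holds no Ensembl number for any of its 47357 genes. It matched 0 of the 32883 identifiers, so no gene symbol, coordinate or neighbour is given. For this reason 39 gene lists fixed before the data were examined, their camera and fry tests, the share of mitochondrially encoded transcripts and the fixed named genes could not be run. The rule for naming genes took the largest rises and falls among genes past the threshold with a mean of at least 50 and a real symbol. Without symbols it was applied without that last condition, in the left ventricle, to the 2 largest rises and the largest fall. The fourth identifier was chosen after its values were seen.

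The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the same genes. In the left ventricle edgeR called 5230 genes, 5019 of them among the 5235 of limma, and DESeq2 called 5564, 5158 of them among these. In the right ventricle edgeR called 3497 genes, 3325 shared with limma, and DESeq2 4115, 3533 shared. Adjusted p values that DESeq2 left undefined, for 20 and 30 genes, were kept so. Other alternatives were the pseudocount, the filter on low values, the scaling, robust and weighted fits, and leaving out each animal in turn or CTL animals C_7000 and C_7005 together (named as in the deposited tables).

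The fits were tested on simulated data, with negative binomial reads drawn from the CTL means, spread and size factors and 200 genes changed by known folds. Far fewer genes changed there than the 5235 and 3574 called in the real ventricles, and the relative spread per gene was capped. The recovery and false calls therefore describe this setting and give no rates for the real calls. In the simulated left ventricle (13917 genes), limma recovered 37 of 67 genes changed 1.5-fold, 52 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 6 false calls. In the simulated right ventricle (13312 genes) it recovered 25 of 67, 54 of 67 and 62 of 66, with 3 false calls. For the simulated difference between ventricles (13083 genes) it recovered 12 of 67, 45 of 67 and 64 of 66, with 9 false calls, and with the animal as a block 5, 40 and 64, with 10 false calls. The simulated left and right libraries were drawn independently, with no spread shared by an animal. The lower recovery with the block therefore does not carry over to the real libraries. In the simulated left ventricle edgeR made 6 false calls, recovering 37, 53 and 64 genes, and DESeq2 made 41, recovering 47, 56 and 65, so its higher counts may hold more false calls.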

Results

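Gene expression was measured by RNA sequencing in the left ventricle with septum and in the right ventricular free wall of 12 rats of strain WI, 6 labelled CTL (read here as control) and 6 labelled DAAO. DAAO is the usual abbreviation of D-amino acid oxidase, an enzyme that makes hydrogen peroxide from D-amino acids and is used in chemogenetic models of oxidative stress. The title of the series speaks of chemogenetic heart failure. The 24 libraries form 4 groups of 6, and each animal gave a left and a right ventricular library. The reads recovered from the deposited normalized counts ranged from 15363539 to 23263897 per library in the left ventricle and from 13280705 to 18777633 in the right ventricle. Recovered reads did not differ between the groups past the threshold in the left ventricle (18393043 ± 2712032 in CTL and 17619335 ± 1631267 in DAAO, SD, n = 6 each, exact permutation p = 0.597, two-sided) or in the right ventricle (exact permutation p = 0.301). The files identify genes by Ensembl number and do not pair the numbers with names, so genes are described here by abundance, size of change, ventricle and animal, and 4 are given by identifier. Animals are named as in the deposited tables, with C_ for CTL and D_ for DAAO before the number. Every DAAO animal has a higher number than every CTL animal. The groups therefore cannot be told apart from anything that goes with the numbers, such as an unlabelled cohort. The term DAAO effect stands here for the difference between the labelled groups.

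The comparison of DAAO with CTL in the left ventricle asked which genes differed in level in the main pumping chamber. Of 14041 genes tested, 5235 (37.3%) changed at the adjusted threshold of limma, 2430 higher and 2805 lower in DAAO. Most changes were moderate: the median absolute log2 fold change of the called genes was 0.55, and 1024 genes changed at least 2-fold, 559 higher and 465 lower. At least 4-fold changes were found for 118 genes that rose and 92 that fell. Among these, 91 of the 118 rises and 76 of the 92 falls separated all 6 DAAO from all 6 CTL libraries. Over all tested genes, 1064 were higher and 1163 lower in every DAAO than in every CTL library, 15.9% of genes against the 0.216% that chance gives for 6 against 6.

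Among the most abundant left ventricular transcripts, falls outnumbered rises. Of 170 genes with a mean normalized count of at least 10000, 87 fell and 23 rose, whereas among the 3842 genes with a mean between 10 and 100, 459 fell and 470 rose. ENSRNOG00000025757, the 8th most abundant gene, was singled out after its values were seen, as the largest fall among the 10 most abundant genes. Its normalized count was 335514 ± 85533 in CTL and 76090 ± 32220 in DAAO (SD, n = 6 each), a log2 fold change of -2.22 (SE 0.30, limma adjusted p = 0.000138), with all 6 DAAO libraries below all 6 CTL libraries. The 10 most abundant genes together held 26.6% ± 3.4 of all normalized counts in CTL and 21.1% ± 2.5 in DAAO (SD, n = 6 each, exact permutation p = 0.0152, two-sided, Benjamini-Hochberg adjusted p = 0.0303 over 6 library measures). With every library scaled to the same total, the left ventricular split moved to 4325 higher and 1631 lower. That scaling moved the median log2 fold change of all genes from 0.01 to 0.21. The predominance of falls among the called genes is therefore relative to the deposited scaling, while ENSRNOG00000025757 fell under each scaling tried.

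By the rule for genes to be named, the largest left ventricular fall was that of ENSRNOG00000012458, from a normalized count of 198 ± 124 in CTL to 7.01 ± 5.40 in DAAO (SD, n = 6 each). Its log2 fold change was -4.44 (SE 0.61, limma adjusted p = 0.000145), with all 6 DAAO libraries below all 6 CTL libraries. The largest rise on the scale of the limma fit was that of ENSRNOG00000057344, with a log2 fold change of 5.99 (SE 1.45, limma adjusted p = 0.00613). Its normalized counts ranged from 18.8 to 2311 in DAAO, and 3 of 6 DAAO libraries, those of D_7138, D_7143 and D_7146, lay above every CTL library. In CTL it ranged from 0 to 3.64 in 5 animals and stood at 113 in animal C_7005. Leaving out 1 animal at a time gave log2 fold changes from 5.29 (without D_7143) to 7.02 (without C_7005). With a pseudocount of 5 the log2 fold change of ENSRNOG00000057344 was 4.51, and with 0.5 it was 6.57. The next largest rise was that of ENSRNOG00000047560, with a log2 fold change of 5.06 (SE 1.65, limma adjusted p = 0.0286). The order of these 2 genes depends on the scale: edgeR gave a log2 fold change of 8.42 for ENSRNOG00000047560 and 5.21 for ENSRNOG00000057344, and DESeq2 gave the same order. It ranged from 0 to 2338 in DAAO and from 0 to 6.07 in CTL, and 4 of 6 DAAO libraries lay above every CTL library, with the highest values again in D_7138, D_7143 and D_7146. Its call was lost when animal C_7000, C_7121, C_7123, D_7138, D_7143 or D_7146 was left out, at limma adjusted p values from 0.0507 to 0.0656, while its log2 fold change stayed between 4.01 and 4.89. The call was also lost among genes with a mean of at least 100 (limma adjusted p = 0.0528) and without C_7000 and C_7005 together (log2 fold change 4.63, limma adjusted p = 0.0642), so it lies close to the threshold.

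Control animals C_7000 and C_7005, whose numbers lie apart from those of the other CTL animals, were set aside as an alternative before the data were examined. On an axis where the mean of the 4 other CTL animals is 0 and that of DAAO is 1, animal C_7000 stood at 0.42 and animal C_7005 at 0.81 in the left ventricle. The 4 other CTL animals stood between -0.01 and 0.10 and the DAAO animals between 0.60 and 1.29. In the limma fit, these 2 animals differed from the 4 other CTL animals in 2211 genes of the left ventricle, 1190 higher and 1021 lower. Without them, DAAO and CTL differed in 6707 left ventricular genes, 3411 higher and 3296 lower, and the genes changed at least 2-fold rose in number from 1024 to 1865.

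**Figure D1:**
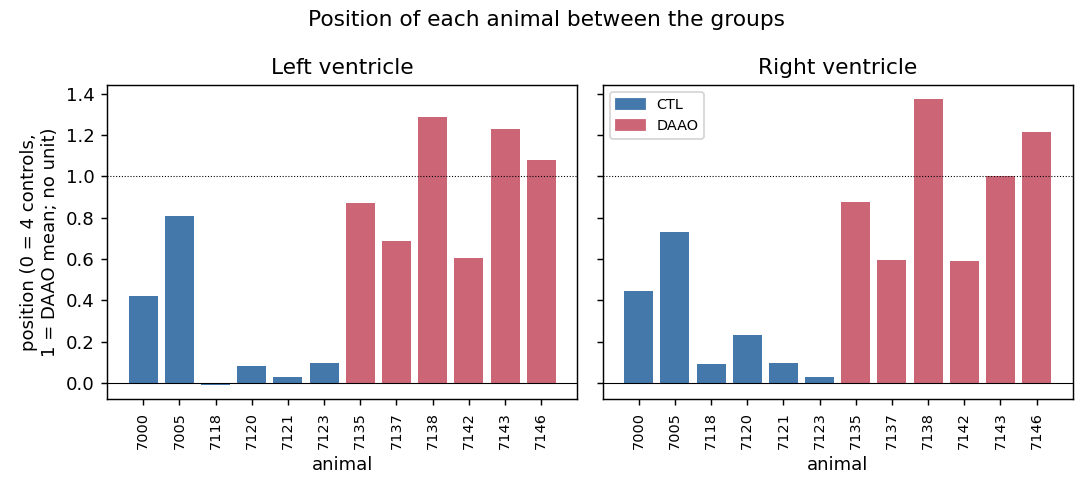
Position of each animal's whole expression profile on the axis from the mean of CTL animals C_7118, C_7120, C_7121 and C_7123 (0) to the DAAO mean (1), without unit, in the left and the right ventricle; each bar is 1 library, left out of the mean it is set against. Animal C_7005 stands at 0.81 and 0.73 and animal C_7000 at 0.42 and 0.44, between the other CTL animals and most DAAO animals.

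In the right ventricle the same comparison was made within its own table. Of 13489 genes tested, 3574 (26.5%) changed at the adjusted threshold of limma, 1684 higher and 1890 lower in DAAO. The median absolute log2 fold change of the called genes was 0.69, and 899 genes changed at least 2-fold, 526 higher and 373 lower. At least 4-fold changes comprised 127 rises and 42 falls, of which 73 and 24 separated all DAAO from all CTL libraries. Over all tested genes, 602 were higher and 742 lower in every DAAO than in every CTL library, 9.96% of genes against 0.216% by chance.

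As in the left ventricle, falls outnumbered rises among the most abundant right ventricular genes, with 54 falls and 11 rises among 138 genes with a mean normalized count of at least 10000, of which 47.1% were called. Among the 3820 genes with a mean between 10 and 100, rises outnumbered falls, 352 to 204. The 10 most abundant genes held 27.8% ± 2.8 of all normalized counts in CTL and 23.0% ± 2.2 in DAAO (SD, n = 6 each, exact permutation p = 0.00866, two-sided, Benjamini-Hochberg adjusted p = 0.0260). More genes were detected in DAAO than in CTL, 17157 ± 532 against 16051 ± 416 (SD, n = 6 each, exact permutation p = 0.00649, two-sided, Benjamini-Hochberg adjusted p = 0.0260). In libraries thinned to 13280705 reads each the numbers were 16937 and 15943 (exact permutation p = 0.00649). In the left ventricle the detected genes, 18393 ± 317 in DAAO and 18282 ± 550 in CTL, did not differ past the threshold (SD, n = 6 each, exact permutation p = 0.680), and the difference between the ventricles in this measure was not tested. Scaling to equal totals gave 3802 higher and 933 lower genes in the right ventricle and moved the median log2 fold change of all genes from 0.02 to 0.27.

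**Figure D2:**
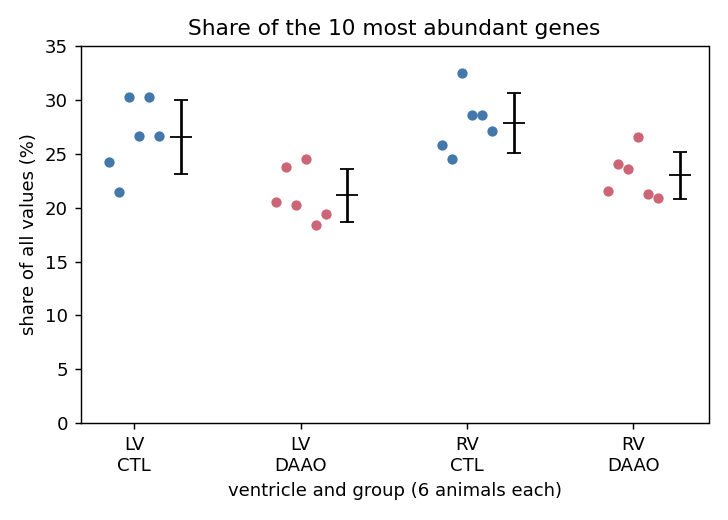
Share of all normalized counts (%) held by the 10 genes with the highest mean in each table; each point is 1 library (6 animals per group), and the bars beside the points show the mean and SD. The means were 26.6% in CTL and 21.1% in DAAO in the left ventricle (LV), and 27.8% and 23.0% in the right ventricle (RV).

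The 4 identified genes changed in the right ventricle in the same direction. ENSRNOG00000025757, 9th in abundance there, fell from 296694 ± 84212 in CTL to 86905 ± 52638 in DAAO (SD, n = 6 each, log2 fold change -2.01, SE 0.42, limma adjusted p = 0.00359), with all 6 DAAO libraries below all CTL libraries. ENSRNOG00000012458 fell from 160 ± 92.8 to 11.94 ± 10.95 (SD, n = 6 each, log2 fold change -4.02, SE 0.71, limma adjusted p = 0.00149), again in 6 of 6. ENSRNOG00000057344 rose with a log2 fold change of 6.99 (SE 1.63, limma adjusted p = 0.00684), and 5 of 6 DAAO libraries lay above every CTL library. It was at 0 in 5 CTL animals and at 54.9 in animal C_7005. Its log2 fold change was 6.27 without D_7146, 8.41 without D_7135 and 5.34 with a pseudocount of 5. ENSRNOG00000047560 was at 0 in all 6 CTL libraries and in 2 of the DAAO libraries and reached 1771 in DAAO (limma adjusted p = 0.0359). That call was lost without animal C_7000, C_7118, C_7120, C_7121, C_7123, D_7138, D_7143 or D_7146, at limma adjusted p values from 0.0549 to 0.0907. With no reads in CTL its log2 fold change is set by the pseudocount and was 5.59 with 1, 6.24 with 0.5 and 4.15 with 5. It was also lost among genes with a mean of at least 100 (limma adjusted p = 0.110) and without C_7000 and C_7005 together (limma adjusted p = 0.0633).

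Animals C_7000 and C_7005 stood apart in the right ventricle as well, at 0.44 and 0.73 on the axis from the 4 other CTL animals to DAAO. The 4 other CTL animals stood between 0.03 and 0.23 and the DAAO animals between 0.59 and 1.37. The limma fit of these 2 against the 4 others called 197 genes, 187 higher and 10 lower. Without them, DAAO and CTL differed in 4143 right ventricular genes, 2150 higher and 1993 lower, of which 1520 changed at least 2-fold.

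The DAAO effects in the ventricles were compared over the 13344 genes tested in both. Across these genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.814 and a Spearman rho of 0.710, and 75.1% had the same sign. Because the ventricles come from the same animals, part of this can arise without a mean difference between the groups. In 100 splits that put equal numbers of CTL and DAAO animals on each side, the median r was 0.50, ranging from 0.18 to 0.85. Differences in response among the DAAO animals do not cancel there, so these are not pure no-effect values. The covariance was 0.358 with the real groups, against a median of 0.036 and a highest value of 0.213 in those splits. Taking the left ventricular effect from 3 animals per group and the right ventricular effect from the 3 others gave a median r of 0.65 and a median covariance of 0.32 over 100 draws. In the limma fits, 1050 genes rose in both ventricles and 1224 fell in both. Independent lists of these sizes would share 301 and 384, values that leave out the shared animals. The balanced splits gave no calls that could overlap, so they supply no such value. With different animals for the ventricles, a median of 132.5 genes rose and 88 fell in both, where independent lists would share medians of 15.5 and 15.0. Another 32 genes were called in both with opposite directions.

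Whether the effect itself differed between the ventricles was tested gene by gene in a limma fit over all 24 libraries. It differed for 391 genes, with a more positive or less negative DAAO effect in the left ventricle for 209 and in the right for 182. For 280 of the 391 the estimated effects had opposite signs in the ventricles, and 31 of these were called in both. The other estimated effects had the same sign in both, larger in size in the left ventricle for 32 genes and in the right for 79, and 17 of these genes were called in both. The median absolute difference was 0.67 on the log2 scale, and 59 genes differed at least 2-fold. With the animal as a block, 1072 genes were called, 569 and 503 by direction, including 388 of the 391. Of the 1072, 577 had estimated effects of opposite sign, 32 of them called in both ventricles. Among those with the same sign, 149 were called in both, so the predominance of opposite signs depends on the fit. None of the 4 identified genes differed between the ventricles, at limma adjusted p values of 0.890, 0.95, 0.893 and 0.905 for ENSRNOG00000057344, ENSRNOG00000047560, ENSRNOG00000012458 and ENSRNOG00000025757. The count of 391 depended on single animals. It was 120 without animal C_7000, 123 without C_7118, 156 without C_7120, 255 without D_7135, 616 without D_7137, 160 without D_7138, 184 without D_7142, 223 without D_7143 and 85 without D_7146.

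**Figure D3:**
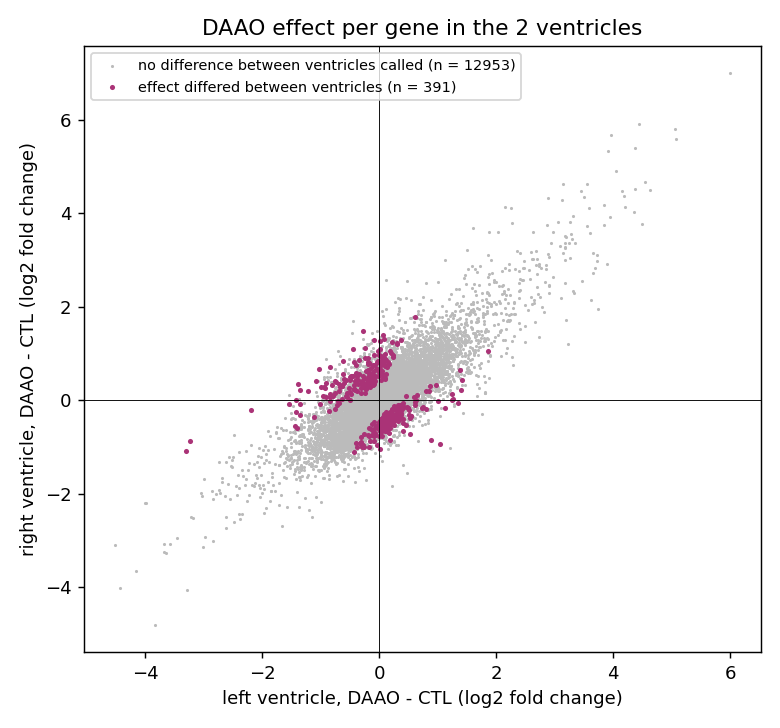
Log2 fold change of DAAO against CTL in the left ventricle (horizontal) and the right ventricle (vertical) for the 13344 genes tested in both, 1 point per gene. The 391 genes whose effect differed between the ventricles in the fit without the block are in purple, and the r across all genes is 0.814. Of the 391, 280 have estimated effects of opposite sign in the ventricles, against 577 of 1072 with the animal as a block.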

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

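The tests in this part were chosen after the results were seen, except the counts over other splits of the animals for the 3 gene counts and the test for left ventricular tissue in right ventricular pieces. ENSRNOG00000057344 stood at 113 in the left ventricle of CTL animal C_7005, far from the 0 to 3.64 of the 5 other CTL animals. In the right ventricle the same animal stood at 54.9 while the 5 others were at 0. ENSRNOG00000047560 reached 2338 in the left ventricle of DAAO animal D_7143, against at most 742 in the 5 other DAAO animals. These were the 3 groups with an animal far from the rest among 28 groups of 6 tested. The nominal chance value of 1.4 does not hold for counts that are 0 in many animals. The flags of C_7005 are also the same gene in both ventricles of that animal, so 3 against 1.4 carries no weight. The DAAO effect differed between the ventricles for 391 genes by the test of the difference itself.

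The labelled groups were set against other splits of the 12 animals into 6 and 6, 100 splits including the real one. The real groups gave 5235 changed genes in the left ventricle, the highest other split 2793, and 1 of 100 splits gave as many. In the right ventricle the counts were 3574 and 492, again 1 of 100. For the difference between the ventricles they were 391 and 0, also 1 of 100, in the fit that ignores the pairing of the libraries by animal. With the animal as a block they were 1072 and 691, again 1 of 100. For the correlation between the ventricles, 3 of 100 splits gave an r of at least 0.814, the highest other being 0.878. Of 462 distinct splits only these 100 were drawn, so the counts within each ventricle and in the blocked fit stand apart from chance at 1 in 100. The other splits mix CTL and DAAO animals. In the fit without the block, a DAAO effect common to both ventricles then adds to the residual spread. Their 0 calls are therefore no fair measure for the 391. For the correlation, chance is set apart only at the limit of 5 in 100, since 2 other splits exceeded the real value. The split with 2793 genes, which also gave the 691, exchanged CTL animal C_7005 with DAAO animal D_7135, so a structure beyond the labels runs through animal C_7005. No exchange of C_7005 with another DAAO animal was among the splits drawn.

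The position of control animals C_7000 and C_7005 toward the DAAO animals was weighed against 3 technical explanations. Scaling or a few abundant genes are argued against, since the lowest position of animal C_7005 over 2 other scalings and without the 10 most abundant genes was 0.684, against at most 0.23 for the 4 other CTL animals as deposited. A swap with a control like the 4 other CTL animals would leave a DAAO animal at their position, but every DAAO animal stood at 0.604 or higher in at least 1 ventricle. This does not cover a swap with a control that lies between the groups, as C_7000 does. In the left and right ventricle, D_7137 (0.69 and 0.60) and D_7142 (0.60 and 0.59) stood below C_7005 (0.81 and 0.73). A wrong label on animal C_7005, as a DAAO animal like the others, is argued against by its left minus right profile. Its mean covariance with the 4 other CTL animals was 0.325, among the 0.317 to 0.389 of these 4 with each other and above the 0.203 to 0.279 of the DAAO animals by more than their SD of 0.030. It lay nearer the DAAO mean in 63.4% of the genes that separate DAAO from the 4 others in the left ventricle and 47.7% in the right, below left-out DAAO animals (from 69.1% and 54.2%), but by less than their SD of 10.3 and 16.5 points. Its ENSRNOG00000025757 stood at 226185 and 291137, above the highest DAAO values of 119125 and 146219, but this gene was chosen with C_7005 among the controls. Its ENSRNOG00000012458 stood at 24.2 and 38.8, near the highest DAAO values of 16.7 and 26.8. The lowest values of the other CTL animals were 85.4 and 96.9. Its ENSRNOG00000057344 stood above that of every other CTL animal. A control that differs, a DAAO animal with a weak response or an unlabelled cohort behind the animal numbers may account for its position and stay open.

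The lower share of the 10 most abundant genes in DAAO did not come from ENSRNOG00000025757 alone: without that gene the exact permutation p was 0.0216 in both ventricles, with differences of -4.52 and -4.03 points. That gene held only 1.73% in CTL and 0.45% in DAAO of the left ventricle, so it could carry only a small part. The most abundant gene, at 7.73% and 8.34% in the ventricles, was not left out. Of the 10 genes, 10 in the left and 9 in the right ventricle had negative log2 fold changes, but limma called only 2 and 1. With log2 recovered reads as a covariate, the share differed by -5.27 points in the left ventricle (SE 1.81, exact permutation p = 0.0152). In the right it differed by -4.51 (SE 1.54, exact permutation p = 0.0238). Its slopes per doubling of reads were 3.16 (SE 5.67) and -4.33 (SE 5.66). A share does not depend on depth in expectation, and reads did not differ between the groups past the threshold. The covariate therefore had little to remove, and this fit is no test of depth. Whether abundant transcripts fell or the others rose cannot be decided from relative values, and a DAAO effect stays among the open explanations, as untested.

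For the 391 genes whose effect differed between the ventricles, a depth gap between the ventricles is argued against, since thinning each animal's deeper library to the reads of the other gave 377 genes, 362 of them among the 391. Left ventricular tissue in the right ventricular pieces of DAAO animals would move right ventricular levels toward the left and leave left ventricular levels in place. Taking the control difference between ventricles from 3 CTL animals and the DAAO effects against the 3 others, the slope of the left ventricular effect on that difference was -0.073 at the median of 20 such splits and below 0 in each (-0.127 to -0.017). The slope of the right ventricular effect was 0.198 (0.096 to 0.263). Such tissue alone would leave the left ventricular slope at 0, so it does not account for that slope. A DAAO effect common to both ventricles could shift both slopes, and the slopes cover all genes tested in both ventricles. They therefore cannot decide whether such tissue made the difference for the 391 genes. An exchange of tissue in both directions during dissection, or a DAAO effect that differs by chamber, may also remain and was not tested.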

How the results depend on the processing

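Of the 102 recomputed values of the main counts, the correlation and the top 10 shares, 86 kept their direction and call or stayed within 1.5 times. Most of those that did not were counts of the ventricle difference. Of 358 other recomputed values, 315 did. By the rule used a count cannot reverse, and 0 of the fold changes, correlations and share differences reversed. With control animals C_7000 and C_7005 alone as controls (chosen after seeing the data), limma called 997 genes in the left and 108 in the right ventricle, with fewer samples and the controls nearest DAAO. Leaving out each animal in turn gave 4411 to 6472 genes in the left and 2587 to 4252 in the right ventricle and r from 0.773 to 0.837. The ventricle difference ranged from 85 to 616 genes. It stood at 236 without animals C_7000 and C_7005, 1101 with array weights and 744 with DESeq2. The cause of these shifts was not tested. With the animal as a replicate block, the only result with a paired fit, it stood at 1072. The block keeps the estimated differences and changes only their error, by taking out spread that the libraries of an animal share (median r 0.55). In CTL animals C_7118, C_7120 and C_7123 this r was only 0.060, 0.057 and 0.254, so little shared spread could be taken out there. The main fit ignores this pairing. The correlation fell to r = 0.687 with no filter on low values, where more genes near 0 enter.

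Scaling to equal totals gave 4325 higher and 1631 lower genes in the left ventricle and 3802 and 933 in the right, against 2430, 2805, 1684 and 1890. Genes changed at least 2-fold, 1024 and 899, became 574 and 544 with a mean of at least 100 (fewer genes tested), 1654 and 1469 with array weights, 1865 and 1520 without animals C_7000 and C_7005, and 1585 in the left ventricle without animal C_7005. Array weights gave 2655 higher genes in the right ventricle. Depth limits genes with low values most. The gene lists, camera and fry tests, the mitochondrial share and the share without the 10 highest nuclear genes were not run, since no symbol matched.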

Other observations

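The tests in this part were chosen after the patterns were seen. The left and right ventricles differed less from each other in DAAO than in CTL animals. For each animal, the left minus right profile over 13344 genes was centred on its median, and the covariance of these profiles between animals of a group measures the difference between the ventricles that the animals share. The mean covariance was 0.357 in CTL and 0.199 in DAAO, equal to a typical shared difference of 0.60 and 0.45 log2 units. Each CTL animal had a mean covariance with its group of 0.333 to 0.383 and each DAAO animal of 0.188 to 0.213, without overlap (exact permutation p = 0.00216, the smallest that this exact test can give). The hypothesis is that DAAO may bring the expression of the ventricles closer together. Right ventricular CTL libraries also had fewer detected genes than DAAO ones, with means of 16051 and 17157. In the left ventricle the means were 18282 and 18393. Whether this difference in the right ventricular libraries made the covariance larger in CTL was not tested. The centring takes out any factor common to a whole library, so the separate scaling of the tables is removed by construction rather than tested. Without control animals C_7000 and C_7005 the covariances were 0.359 and 0.199 (exact permutation p = 0.00476). On a single simulated data set with no effect the same test gave an exact permutation p of 0.0541, with covariances of 0.391 in CTL and 0.379 in DAAO. On another, with the DAAO difference set to 0.75 of that in CTL, the exact permutation p was 0.00216. Single draws without spread shared by an animal cannot show how often the test errs. Left and right libraries of the same number matched less in 4 CTL animals than in any DAAO animal. That this made the difference is argued against: with right ventricular libraries reassigned among the animals of each group, 99 draws gave covariances of 0.294 to 0.362 in CTL and 0.113 to 0.184 in DAAO, at least 0.127 apart. The levels set side by side come from separately normalized tables, and dissection was not tested here beyond the slopes given above.

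Some genes were very high in a few animals and low in the rest, in both ventricles. Among the genes tested in both, 79 had a gap of over 2 log2 units between neighbouring animals in each ventricle, and 32 of them divided the animals in the same way on both sides. Reassigning the right ventricular libraries among animals of a group gave at most 22 such genes, and 1 of 100 draws, the real one, gave 32, which is consistent with a property of the animal that both ventricles share. The most frequent division, in 10 genes, set CTL animal C_7005 and DAAO animals D_7138, D_7143 and D_7146 above the 8 others, by 4.1 to 7.8 log2 units between medians in the left ventricle. The mean normalized count in the high animals ranged from 94.4 to 32685 there, and limma called 0 of these genes between DAAO and CTL in the left and 1 in the right ventricle. The DAAO animals of this division are those with the highest values of ENSRNOG00000057344 and ENSRNOG00000047560. The labels give no sex, and without gene names no sex-linked gene could be examined. Another tissue in the pieces of these animals and a genetic difference were not tested and may each account for it, and without gene names they stay open. A stronger response to DAAO would not by itself place CTL animal C_7005 among the high animals, if its label is right.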
